A study of Homo sapiens with 24 samples.

How the data were processed

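Polyadenylated RNA of human skeletal muscle biopsies was sequenced in 24 libraries, 10 from subjects with prediabetes and 14 from controls, each from a separate subject. Per the labels, RNA was extracted with phenol-based reagents and columns, and stranded paired-end libraries were read on a NovaSeq instrument. The aligner, the counter, the annotation release and the strand setting are not given in the sources used here. The genome build is GRCh38.p14 per the submitters' processing notes. The groups were taken from the sample titles.

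The deposited table of raw counts holds whole-number counts per Ensembl gene, without normalization by the authors, for 63241 identifiers. The second table deposited by the authors holds a normalized signal for 30113 genes, those with at least 10 counts summed over the libraries. It was checked that each of its values is the raw count divided by 1 size factor per library, equal to the DESeq2 median-of-ratios factor. All tests used the raw counts. Totals ranged from 37.6 to 82.9 M (mega-counts) per library, and genes of low level, such as GDF15, rest on few counts. Gene names came from a table of Ensembl identifiers and symbols, which matched 62666 identifiers, and the identifiers without a match in it held 0.0232% of counts. Positions came from GENCODE 29 (GRCh38), which matched 58228 identifiers. Before any test, 526 sex-linked genes were left out because their levels could reveal a person's sex. Among 276 pairs of libraries no duplicate was found.

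Genes were tested with the edgeR (4.0.16) quasi-likelihood F-test with robust fitting, TMM normalization and filterByExpr, in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The filter left 17713 genes, or 17822 without prediabetes libraries 7 and 8. The standard error of a log2 fold change was its size divided by the square root of F. Gene lists were tested with camera of limma (3.58.1) with a preset correlation of 0.01, adjusted over the 53 of 54 lists with at least 3 measured members; the skin marker list had fewer and gave no test. Members were also adjusted over the list alone. Indices were the mean log2 CPM (TMM, prior count 2) of a list, and they and the depth and composition were compared by two-sided permutation tests with 100000 resamples.

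The design, the lists, the rule for named genes and the other settings to try were fixed before the data were examined. By that rule the text names up to 10 genes per direction that pass the test with a mean log2 CPM of at least 0. Failing that, it names those of smallest p at that level. Genes of either kind must have an unadjusted p below 0.05 and the same sign in each fit leaving out 1 library. The text further names the 4 members of smallest p of each called list, up to 2 of other lists, and 15 fixed genes. Genes of donor-specific presence or alleles were excluded, and 2 members of called lists that the rule selects are not reported here. Members selected only for lists called in neither set are not named in the text, GDF11 excepted.

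The other settings were DESeq2 (1.42.0) size factors and its Wald test, limma-voom with and without sample weights, no low count filter or an average CPM of at least 1, covariates (fibre index, sex-linked transcripts, log2 depth, surrogate variables from sva 3.50.0), an adjusted p threshold of 0.1, an estimated correlation or fry for lists, a prior count of 0.5, and each library left out in turn. Leaving out prediabetes libraries 7 and 8 together, and an adipocyte covariate, were added after seeing the data. For 24 and for 22 libraries, 100 splits into groups of the same sizes, the real one included, were fitted. The pipeline was tested on simulated data: with 24 libraries edgeR recovered 40%, 68%, 92% and 96% of 50 genes changed 1.5-fold, 2-fold, 4-fold and 8-fold, and called 11 of 17483 unchanged genes. The simulation drew each gene on its own, without the shifts shared by libraries 7 and 8: 4.84% of its unchanged genes had an unadjusted p under 0.05, against 16.2% of genes in the data. Its recovery is therefore no estimate for the real libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.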

Results

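The transcriptome of human skeletal muscle biopsies was profiled by bulk sequencing of polyadenylated RNA in 24 libraries, 10 from subjects with prediabetes and 14 from control subjects. Prediabetes is a state of raised blood glucose below the threshold for diabetes, and the comparison asks which muscle transcripts differ between both groups. Each library held between 37.6 and 82.9 M gene counts (M, mega-counts). The mean depth was 58.0 ± 9.44 M (SD, n = 14) in controls and 54.8 ± 8.05 M (SD, n = 10) in prediabetes, a difference smaller than the spread between libraries (two-sided permutation test, p = 0.397). The groups are separate subjects, so the p-values of single genes and of permutation tests rest on the spread between persons. The list p-values under a preset correlation instead compare the genes of a list with the other genes, taken as nearly independent. Those list p-values do not by themselves measure the spread between persons.

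Prediabetes libraries 7 and 8 stood apart from the other 22 in their tissue markers. ACTA1, the skeletal muscle actin, was at 15313 and 48.5 CPM of the library total in libraries 7 and 8, against 23588 to 41153 CPM in the other 22. The creatine kinase gene CKM was at 8262 and 26.2 CPM against 16316 to 28514 CPM, and the myoglobin gene MB at 4980 and 13.8 CPM against 8769 to 12845 CPM. The adipocyte hormone gene ADIPOQ showed the opposite order, at 1381 and 3592 CPM against 0.903 to 280 CPM, and the lipid droplet gene PLIN1 was at 1368 and 3357 CPM against 2.32 to 253 CPM. The collagen gene COL1A1 was at 1527 and 1092 CPM against 20.8 to 171 CPM, and the haemoglobin gene HBB at 10914 and 1983 CPM against 21.8 to 1111 CPM. Their depths of 70.7 and 56.2 M counts lay within the range of the others. Their median Spearman correlation with the remaining libraries was 0.908 and 0.793, against a median of 0.976 among pairs of the other 22 (correlations across genes, which are not independent replicates). The first principal component, which took 47.5% of the variance, separated them from the rest. Both libraries stayed in the comparison as planned, and the counts of genes with edgeR and of lists called are also given for the 22 libraries without them, an alternative chosen after the data were seen.

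**Figure D1:**
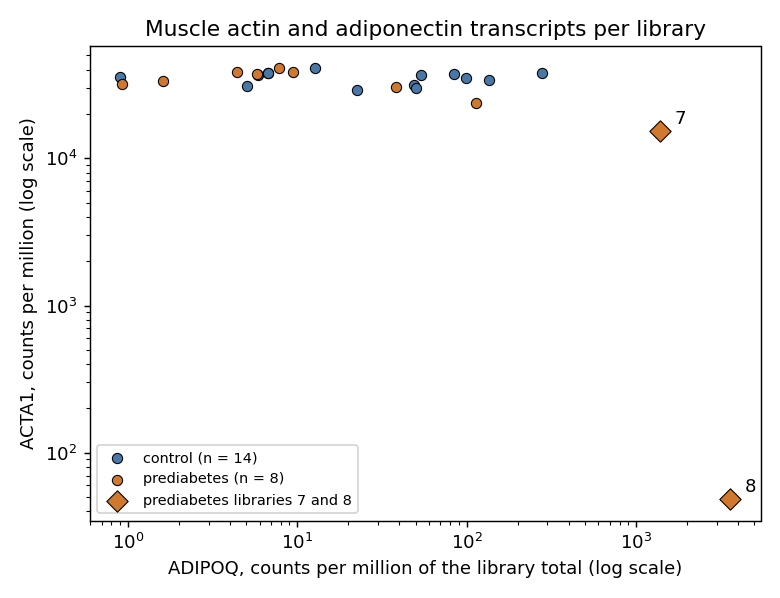
CPM of ADIPOQ (adiponectin, horizontal axis) and ACTA1 (skeletal muscle actin, vertical axis) in each library, both on log scales and relative to the library total. Each point is 1 library, blue for control and orange for prediabetes, and the diamonds mark prediabetes libraries 7 and 8, which had ADIPOQ at 1381 and 3592 CPM and ACTA1 at 15313 and 48.5 CPM.

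No gene passed the adjusted threshold between prediabetes and control muscle with edgeR without covariates, and the gene with the smallest p was ABCC6. ABCC6, a transporter gene (ENSG00000091262, chromosome 16, positions 16148928 to 16223522 on the minus strand of GRCh38), was at 1.92 ± 0.742 CPM in controls and 6.0 ± 3.12 CPM in prediabetes (SD, n = 14 and 10). Its log2 fold change was 1.64 ± 0.29 (SE) with an edgeR adjusted p of 0.104. Its level was above the control median in 9 of 10 prediabetes libraries, and without libraries 7 and 8 the log2 fold change was 1.57 (edgeR adjusted p = 0.612). ABCC6 has pseudogene copies with which reads can be shared, so its level is uncertain. Among the genes with the next smallest p and a positive fold were markers of tissue macrophages. On the log2 scale MARCO was at 2.15 ± 0.51 (SE), C1QB at 1.83 ± 0.42 (SE) and C1QC at 1.61 ± 0.40 (SE). VSIG4 was at 1.45 ± 0.37 (SE), MRC1 at 1.35 ± 0.34 (SE) and CD163 at 1.34 ± 0.32 (SE) (edgeR adjusted p = 0.256 for each of the 6). The same direction held for EMILIN2, an elastin-associated matrix gene, at 2.0, SEMA6A, a semaphorin, at 0.79, and RTL8B at 0.47. Without libraries 7 and 8 these 3 stood at 0.47 (unadjusted p = 0.118), 0.38 and 0.34, and MARCO, C1QB, C1QC, VSIG4, MRC1 and CD163 at 1.26, 0.64, 0.54, 0.61, 0.52 and 0.63. On the negative side, NR4A3 and ATF3, transcription factor genes induced by exercise and stress, had log2 fold changes of -3.24 ± 0.90 (SE) and -1.94 ± 0.54 (SE) (edgeR adjusted p = 0.256 for each). NR4A3 was at 55.2 ± 128 CPM in controls and 5.83 ± 4.99 CPM in prediabetes (SD), and the control mean rested on a few high libraries. MTND4P12, a pseudogene copy of MT-ND4 whose reads can be shared with it, was at -2.33. Smaller negative values were found for FAM161A (-0.63), the potassium-dependent sodium-calcium exchanger gene SLC24A3 (-0.56), the ubiquitin ligase gene NEDD4L (-0.53), the mitochondrial fission gene GDAP1 (-0.45), ZNF239 (-0.42), HSPBAP1 (-0.39) and C9orf72 (-0.35), the last with an adjusted p of 0.256. GDAP1, HSPBAP1 and MTND4P12 were below the control median in 10 of 10 prediabetes libraries after TMM scaling. The TMM factors of libraries 7 and 8 were 1.48 and 2.11. Relative to the library total, GDAP1 was at 7.15 CPM in library 8, against 2.73 to 5.66 CPM in the other 22. Its count of 10 thus depended on the scaling. HSPBAP1 was at 14.1 and 15.4 CPM in libraries 7 and 8, both above the median of the other 22. The naming rule admitted only genes with an unadjusted p under 0.05 and the same sign whichever single library was left out. That these 20 genes met this condition is therefore no added support for them.

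Of 17713 genes tested with edgeR, 0 had an adjusted p below 0.05 and 2875 had an unadjusted p below 0.05, 2429 higher and 446 lower, where chance would give about 886. Without prediabetes libraries 7 and 8, 0 of 17822 genes passed and 852 had an unadjusted p below 0.05, 346 higher and 506 lower, of which 332 were shared in direction with those of all 24 libraries. Leaving out library 7 alone gave 1190 such genes and leaving out library 8 alone gave 1101. The DESeq2 Wald test called 2 genes, ABCC6 (log2 fold change 1.63, adjusted p = 3.09e-04) and the RNA-binding protein gene ELAVL2 (log2 fold change -3.06, adjusted p = 0.0101), the latter named after its value was seen, and 2891 had an unadjusted p under 0.05. Limma-voom called 0, with 1955 at an unadjusted p under 0.05, and 0 with sample weights, with 931. With edgeR, ABCC6 was called when prediabetes 3 (adjusted p = 0.0301), prediabetes 4 (0.0333), prediabetes 10 (0.0184) or control 11 (0.0496) was left out. Without control 11, CCDC144NL-AS1, an antisense RNA whose reads can belong to a neighbouring gene, was called as well (adjusted p = 0.00836), and it was named after its value was seen. With the adipocyte index as a covariate, a setting chosen after the data were seen, edgeR called 580 genes in 24 libraries, 481 higher and 99 lower. Among them were ABCC6, C1QB, C1QC, MRC1 and CD163 (adjusted p = 0.0176 for each), VSIG4 (0.0246) and MARCO (0.0268). With the same covariate in 22 libraries it called 0, with 1232 at an unadjusted p under 0.05.

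Genes fixed in advance for muscle mass and glucose handling had no adjusted p below 0.05 with edgeR without covariates. MSTN, which encodes the growth inhibitor myostatin, was at 5.26 ± 4.07 CPM in controls and 5.37 ± 2.05 CPM in prediabetes (SD, n = 14 and 10). The atrophy ligase genes FBXO32 and TRIM63 had log2 fold changes of -0.43 ± 0.34 (SE) and -0.61 ± 0.50 (SE). The insulin receptor substrate genes IRS1 and IRS2 were at -0.48 ± 0.17 (SE) and -0.42 ± 0.26 (SE), with edgeR adjusted p of 0.256 and 0.409. IRS1 was below the control median in 8 of 10 prediabetes libraries after TMM scaling and stood at -0.35 without libraries 7 and 8. It was called with the adipocyte covariate in 24 libraries (-0.53, adjusted p = 0.0484) and not in 22 (-0.46, adjusted p = 0.595). The glucose transporter gene SLC2A4 was at -0.38 ± 0.26 (SE), the hexokinase gene HK2 at 0.11 ± 0.22 (SE) and the pyruvate dehydrogenase kinase gene PDK4 at -0.49 ± 0.37 (SE). PPARGC1A, a regulator of mitochondrial biogenesis, was at -1.04 ± 0.51 (SE) (edgeR adjusted p = 0.310). The myosin heavy chain genes were at -0.10 ± 0.49 (SE) for MYH7 of slow fibres, -0.29 ± 0.58 (SE) for MYH2 and -0.40 ± 0.67 (SE) for MYH1 of fast fibres. The collagen genes COL1A1 and COL3A1 were at 1.52 ± 0.46 (SE) and 1.08 ± 0.36 (SE), and at 0.09 and 0.09 without libraries 7 and 8. The stress cytokine gene GDF15 was at 0.187 ± 0.0891 CPM in controls and 0.232 ± 0.118 CPM in prediabetes (SD). These values include libraries 7 and 8 except where stated. Relative to the library total, SLC2A4 was at 35.7 and 13.1 CPM in them, against 68.6 to 94.8 CPM in the other 22. FBXO32, PPARGC1A and MYH7 were also below their ranges in both. TRIM63 was at 0.800 CPM in library 8, against 64.9 to 509 CPM. HK2, GDF15, COL1A1 and COL3A1 were above their ranges in both, and MSTN, PDK4 and IRS1 within them.

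Among 53 gene lists fixed in advance, connective tissue, macrophage, endothelial and lipid storage lists were called higher in prediabetes, and contractile, mitochondrial and carbohydrate lists lower, by limma's camera test with a preset correlation. This test called 33 lists, 9 higher and 24 lower. With the correlation estimated it called 0 (smallest adjusted p = 0.534), with 0 lists at an unadjusted p under 0.05, and fry, a test of the list's own genes, called 0 (smallest adjusted p = 0.358, with 3 lists at an unadjusted p under 0.05). Without prediabetes libraries 7 and 8 the preset test called 10 lists, 3 higher and 7 lower, and 4 of the 33 were called again in the same direction. The other 29 were not, including 2 that were called in the opposite direction. In the same 22 libraries 0 lists were called with an estimated correlation (smallest adjusted p = 0.411, with 4 at an unadjusted p under 0.05) or with fry (smallest adjusted p = 0.489, with 4). Over all genes tested, no member of any list passed edgeR's adjusted threshold, so log2 fold changes of members below are values and not calls. Adjusted over the list alone, members passed in 6 of the 33 called lists (extracellular matrix, fibroblast, macrophage, tendon, neutrophil and mast cell, and immediate early) and in 0 of the other 27. Of the lists not called, ER stress, metallothioneins, myostatin and myokines had 1 such member each.

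**Figure D2:**
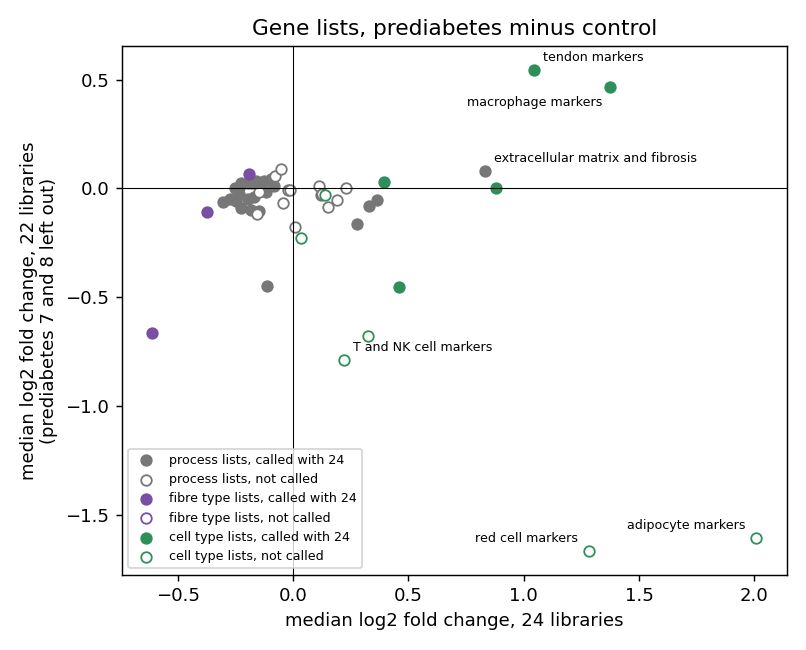
Median log2 fold change (prediabetes minus control) of each of the 53 gene lists with all 24 libraries (horizontal axis) and with the 22 libraries left without prediabetes 7 and 8 (vertical axis). Each point is 1 list, filled where camera with a preset correlation called it in 24 libraries. The macrophage list was positive on both axes (1.37 and 0.47), and the adipocyte list was at 2.01 and -1.61.

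Contractile and muscle structure lists were lower with all 24 libraries. The slow fibre list was called lower in prediabetes (adjusted p = 7.72e-04; adjusted p = 0.534 with an estimated correlation), with 11 of 11 measured members below 0. Its log2 fold changes included -0.35 for MYH7B, -0.32 for MYL2, -0.20 for CASQ2 and -0.19 for TPM3. The fast fibre list was called lower in prediabetes (adjusted p = 1.12e-04; adjusted p = 0.534 with an estimated correlation), with 14 of 14 measured members below 0. Members of smallest p stood at -2.94 for MYH4, -0.42 for TNNT3, -0.42 for MYL11 and -0.39 for MYL1. MYH4, the fastest myosin, was at 19.2 ± 47.0 CPM in controls and 2.50 ± 2.15 CPM in prediabetes (SD). The sarcomere and Z-disc list was called lower in prediabetes (adjusted p = 2.45e-07; adjusted p = 0.534 with an estimated correlation), with 24 of 24 measured members below 0. Log2 fold changes were -1.13 for XIRP1, -0.18 for CAPZA2, -0.53 for LMOD2 and -0.09 for CAPZB. XIRP1 encodes an actin-binding protein of muscle. The calcium handling list was called lower in prediabetes (adjusted p = 3.09e-04; adjusted p = 0.534 with an estimated correlation), with 18 of 20 measured members below 0. Values of its members included 0.31 for FKBP1A, -0.50 for SLN, -0.24 for ORAI1 and -0.30 for CACNA2D1. SLN encodes the calcium pump regulator sarcolipin. The neuromuscular junction list was called lower in prediabetes (adjusted p = 1.25e-04; adjusted p = 0.534 with an estimated correlation), with 17 of 18 measured members below 0. Among its members the log2 fold change was 0.46 for AGRN, -0.44 for HDAC9, -0.36 for GADD45A and -0.67 for MUSK. The satellite cell and myogenesis list was called lower in prediabetes (adjusted p = 5.91e-05; adjusted p = 0.534 with an estimated correlation), with 13 of 14 measured members below 0. Its log2 fold changes included -0.26 for MEF2A, -0.76 for MYF6, -0.45 for EYA1 and -0.32 for MEF2D. None of these 6 lists was called without prediabetes libraries 7 and 8 (adjusted p = 0.213 for the slow fibre, neuromuscular junction and satellite cell lists, 0.428 for calcium handling, 0.503 for fast fibre and 0.741 for sarcomere). The slow fibre, sarcomere and calcium handling lists then turned to the higher side. The slow fibre call was also lost without prediabetes 8 (adjusted p = 0.113). With 3 surrogate variables as covariates these 3 lists were called higher (adjusted p = 0.0116, 0.0189 and 0.00641 for slow fibre, sarcomere and calcium handling). Those calls used the preset correlation, and an estimated one was not fitted with surrogate variables; without covariates it was 0.930, 0.899 and 0.568 within these lists, and 0 lists were called with it. The list of developmental and regenerating fibre genes was called lower both with 24 libraries (adjusted p = 0.00452; adjusted p = 0.534 with an estimated correlation) and without libraries 7 and 8 (adjusted p = 0.00726; adjusted p = 0.557 with an estimated correlation). Its median log2 fold change over 8 members was -0.61 and -0.66. The perinatal myosin gene MYH8 was at -0.97, the cardiac troponin gene TNNT2 at -1.48 and MYL5 at -0.77, while the myoblast fusion gene MYMX was at 2.12 with 24 libraries and -1.13 without both.

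Mitochondrial lists were likewise lower with all 24 libraries. The nuclear complex I list was called lower in prediabetes (adjusted p = 5.33e-06; adjusted p = 0.534 with an estimated correlation), with 33 of 37 measured members below 0. Members of smallest p stood at -0.24 for NDUFV3, -0.37 for NDUFS1, 0.23 for NDUFA13 and -0.23 for NDUFS4. The nuclear complex II to V list was called lower in prediabetes (adjusted p = 4.05e-08; adjusted p = 0.534 with an estimated correlation), with 40 of 41 measured members below 0. Log2 fold changes were 0.77 for COX6A1, -0.24 for ATP5MC2, -0.25 for ATP5ME and -0.37 for COX7A1. NDUFA13 and COX6A1 overlap other genes and had few counts, so their levels are uncertain. The mitochondrially encoded OXPHOS list was called lower in prediabetes (adjusted p = 2.92e-04; adjusted p = 0.534 with an estimated correlation), with 13 of 13 measured members below 0. Values of its members included -0.48 for MT-ND6, -0.26 for MT-ND1, -0.26 for MT-CO3 and -0.27 for MT-CO1. The TCA cycle and pyruvate oxidation list was called lower in prediabetes (adjusted p = 2.96e-05; adjusted p = 0.534 with an estimated correlation), with 21 of 22 measured members below 0. Among its members the log2 fold change was 0.53 for PC, -0.35 for SUCLG2, -0.30 for PDHB and -0.29 for DLD. The mitochondrial biogenesis list was called lower in prediabetes (adjusted p = 3.70e-04; adjusted p = 0.534 with an estimated correlation), with 18 of 22 measured members below 0. Its log2 fold changes included -1.04 for PPARGC1A, -0.69 for ESRRG, -0.20 for SIRT1 and -0.21 for SIRT3. ESRRG encodes an orphan nuclear receptor of oxidative muscle. The mitochondrial dynamics list was called lower in prediabetes (adjusted p = 0.0142; adjusted p = 0.560 with an estimated correlation), with 15 of 18 measured members below 0. Members of smallest p stood at 0.56 for BNIP3L, 0.13 for MIEF1, -0.19 for PHB2 and -0.21 for OMA1. The mitochondrial ribosomal protein list was called lower in prediabetes (adjusted p = 2.17e-05; adjusted p = 0.560 with an estimated correlation), with 40 of 47 measured members below 0. Log2 fold changes were -0.14 for MRPL32, -0.20 for MRPS27, -0.14 for MRPL10 and -0.32 for MRPS28. Without libraries 7 and 8, the mitochondrial ribosomal protein list was called higher instead (median 0.03, adjusted p = 0.0423; adjusted p = 0.891 with an estimated correlation), and the other 6 were not called (adjusted p from 0.154 to 0.758). Of those 6, the mitochondrially encoded list stayed on the lower side and 5 turned to the higher side. The call of mitochondrial dynamics was also lost without prediabetes 7 (adjusted p = 0.0922) and prediabetes 8 (adjusted p = 0.358).

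Lists of carbohydrate and amino acid metabolism followed the same direction with 24 libraries. The glycolysis list was called lower in prediabetes (adjusted p = 3.43e-04; adjusted p = 0.534 with an estimated correlation), with 16 of 18 measured members below 0. Values of its members included -0.37 for LDHA, -0.41 for PKM, -0.25 for PGK1 and -0.20 for PFKFB1. The glycogen list was called lower in prediabetes (adjusted p = 3.70e-04; adjusted p = 0.534 with an estimated correlation), with 15 of 17 measured members below 0. Among its members the log2 fold change was -0.37 for STBD1, -0.36 for PGM1, -0.32 for GYG1 and 0.10 for GAA. The branched chain amino acid breakdown list was called lower in prediabetes (adjusted p = 3.23e-05; adjusted p = 0.534 with an estimated correlation), with 17 of 19 measured members below 0. Its log2 fold changes included -0.31 for IVD, -0.37 for ACADSB and -0.32 for BCKDK. The creatine and purine nucleotide list was called lower in prediabetes (adjusted p = 1.48e-05; adjusted p = 0.534 with an estimated correlation), with 14 of 14 measured members below 0. Members of smallest p stood at -0.39 for NAMPT, -0.41 for GATM, -0.17 for NADK2 and -0.33 for ADSL. The circadian clock list was called lower in prediabetes (adjusted p = 0.00621; adjusted p = 0.534 with an estimated correlation), with 15 of 19 measured members below 0. Log2 fold changes were -0.50 for RORA, 0.26 for HLF and -0.33 for BHLHE41. Lipid storage and synthesis was called higher (adjusted p = 0.0270; adjusted p = 0.545 with an estimated correlation), with 22 of 25 members above 0 and log2 fold changes of 2.10 for LIPE, 1.32 for AGPAT2, 2.73 for SCD and 1.2 for GPAM. In libraries 7 and 8 the adipocyte marker ADIPOQ was at 1381 and 3592 CPM, and without both libraries SCD was at -2.09 and LIPE at -0.95. None of these 6 lists was called without libraries 7 and 8 (adjusted p from 0.154 to 0.758), and the glycogen and lipid storage lists changed direction. The lipid storage call was also lost without prediabetes 2 (adjusted p = 0.0638), prediabetes 7 (adjusted p = 0.157) and prediabetes 8 (adjusted p = 0.231).

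Cytosolic ribosomal protein genes were called lower as a list both with 24 libraries (adjusted p = 2.88e-13; adjusted p = 0.534 with an estimated correlation) and without libraries 7 and 8 (adjusted p = 3.24e-11; adjusted p = 0.867 with an estimated correlation). The shift was small, with median log2 fold changes of -0.15 and -0.10 and 72 of 76 members below 0 with 24 libraries, among them -0.28 for RPS15A, -0.19 for RPL22, -0.25 for RPL35 and -0.25 for RPS16. The translation and mTOR list was called lower in prediabetes (adjusted p = 0.00285; adjusted p = 0.534 with an estimated correlation), with 26 of 36 measured members below 0. Values of its members included -0.92 for DDIT4L, -0.20 for TSC1, 0.12 for EIF2B1 and -0.26 for EIF4EBP1. DDIT4L, an inhibitor of mTOR signalling, was below the control median in 10 of 10 prediabetes libraries after TMM scaling. The ubiquitin ligase and atrophy list was called lower in prediabetes (adjusted p = 8.92e-07; adjusted p = 0.534 with an estimated correlation), with 28 of 31 measured members below 0. Among its members the log2 fold change was -0.41 for ZFAND5, -0.61 for NEDD4, -0.35 for FBXO30 and -0.55 for UBE2D1. The heat shock list was called lower in prediabetes (adjusted p = 2.16e-04; adjusted p = 0.534 with an estimated correlation), with 23 of 26 measured members below 0. Its log2 fold changes included -0.57 for DNAJB4, -0.55 for HSPB8, -0.32 for HSPB6 and -0.23 for HSPH1. These last 3 lists were not called without libraries 7 and 8 (adjusted p = 0.524, 0.189 and 0.274). Proteasome subunits were not called with 24 libraries (adjusted p = 0.0700) and were called higher without both (median 0.09, adjusted p = 3.61e-10; adjusted p = 0.557 with an estimated correlation). PSMB7 and PSMB5 then stood at 0.02 and 0.04. Immediate early and biopsy stress genes were called lower in both sets (24 libraries: adjusted p = 0.0452, and adjusted p = 0.574 with an estimated correlation; 22 libraries: adjusted p = 2.29e-09, and adjusted p = 0.411 with an estimated correlation). NR4A3 and ATF3 passed adjusted over the list alone with 24 libraries and 4 of 24 members did without libraries 7 and 8. With 24 libraries NR4A1 was at -1.23 and KLF4 at 0.91, and 14 members of the list were below 0 and 10 above. Its median log2 fold change was -0.11 with 24 libraries and -0.45 without libraries 7 and 8. The call in 24 libraries was lost without any one of control 2, 6, 7, 8 and 10 or prediabetes 1, 2, 3, 5, 6, 9 and 10 (adjusted p from 0.0508 to 0.380, the highest without prediabetes 9).

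Connective tissue genes were called higher with 24 libraries. In the extracellular matrix list, 37 of 37 members were above 0 and 30 passed adjusted over the list alone, against 0 over all genes (list adjusted p = 6.16e-12; adjusted p = 0.534 with an estimated correlation). Its members included the fibrillin gene FBN1 at 1.78, the collagen crosslinking enzyme gene LOX at 1.89, COL1A1 at 1.52 and COL1A2 at 1.2. Without libraries 7 and 8 its median went from 0.83 to 0.08 and 0 members passed (list adjusted p = 0.433). The fibroblast list was called higher (adjusted p = 1.74e-04; adjusted p = 0.534 with an estimated correlation), 8 of 13 members passing over the list alone, with 1.78 for FBN1, 1.45 for PI16, 1.47 for DPP4 and 0.48 for FAP. Without libraries 7 and 8 the 4 genes stood at 0.50, 0.21, 0.43 and 0.43, and the list's median went from 0.88 to 0.00268. Tendon markers were called higher (adjusted p = 0.0452; adjusted p = 0.534 with an estimated correlation), 5 of 9 passing over the list alone, with 1.96 for FMOD, 0.94 for COL12A1, 1.62 for MKX and 2.79 for COMP. Endothelial markers were called higher (adjusted p = 2.96e-05; adjusted p = 0.534 with an estimated correlation), 14 of 14 above 0, with 0.84 for AQP1, 0.74 for PECAM1, 0.54 for MMRN2 and 0.52 for ERG. None of these 4 lists was called without libraries 7 and 8 (adjusted p = 0.433, 0.735, 0.0926 and 0.649). The tendon call was also lost without any one of control 1, 2, 7, 9, 10, 12 and 13 or prediabetes 4, 5, 7 and 10 (adjusted p from 0.0506 to 0.230, the highest without prediabetes 10).

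Macrophage markers were called higher in both sets of libraries. With 24 libraries, 14 of 14 markers were above 0 and 14 passed adjusted over the list alone, against 0 over all genes (median log2 fold change 1.37, list adjusted p = 4.25e-11; adjusted p = 0.534 with an estimated correlation). The complement genes C1QB and C1QC and the scavenger receptor genes MARCO and CD163 led the list. Without libraries 7 and 8 the median was 0.47 (list adjusted p = 2.37e-06; adjusted p = 0.710 with an estimated correlation), 0 members passed over the list alone, and the 4 genes stood at 0.64, 0.54, 1.26 and 0.63. CD163, 1 of the 14 markers, was above the control median in 7 of the remaining 8 prediabetes libraries. The macrophage index, the mean log2 CPM of the markers, varied more around the control median of 1.36. It was at 1.72, 1.40, 1.08, 2.44, 2.26 and 0.462 in prediabetes 1 to 6, and at 1.15 and 2.84 in prediabetes 9 and 10. Inflammation and NF-kB genes were called higher with 24 libraries (adjusted p = 0.0467; adjusted p = 0.607 with an estimated correlation), with 0.64 for IL1R1, 0.51 for TLR4, 0.71 for MYD88 and 0.44 for TNFSF10, and lower without both libraries (adjusted p = 0.0435; adjusted p = 0.867 with an estimated correlation). The interferon list was called higher (adjusted p = 0.0141; adjusted p = 0.617 with an estimated correlation), with -0.27 for IFIT1, 0.50 for IFITM3, 0.47 for PSMB8 and 0.51 for IFITM1. Neutrophil and mast cell markers were called higher (adjusted p = 0.0289; adjusted p = 0.574 with an estimated correlation), 4 of 12 members passing over the list alone, the mast cell genes MS4A2, HDC, TPSAB1 and TPSB2 at 1.13, 1.12, 1.16 and 1.46. Tryptase genes such as TPSAB1 and TPSB2 are near-identical copies, so their levels are uncertain. The interferon and the neutrophil and mast cell lists were on the lower side without libraries 7 and 8 (adjusted p = 0.0645 and 0.388). The inflammation call was also lost without any one of control 1, 3, 4, 5, 6, 9 and 13 or prediabetes 7 and 8 (adjusted p from 0.0521 to 0.574, the highest without prediabetes 8). The interferon call was lost without control 6 (adjusted p = 0.0670), prediabetes 7 (adjusted p = 0.291) and prediabetes 8 (adjusted p = 0.336). The neutrophil and mast cell call was lost without any one of control 6, 9, 10 and 13 or prediabetes 7 and 8 (adjusted p from 0.0513 to 0.291, the highest without prediabetes 7).

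Adipocyte, T and NK cell, and red cell markers were called lower in prediabetes without libraries 7 and 8, but not with all 24. The adipocyte list had a median log2 fold change of -1.61 in 22 libraries (adjusted p = 1.57e-09; adjusted p = 0.411 with an estimated correlation) and 2.01 in 24 (adjusted p = 0.228), with FABP4 at -0.71 and 1.79, and PLIN4 at -0.05 and 1.17. The T and NK cell list was at -0.79 (adjusted p = 1.64e-10; adjusted p = 0.411 with an estimated correlation) and 0.22 (adjusted p = 0.792), with CD3G at -0.85 and 0.56, and CD4 at -0.15 and 1.27. Red cell markers were at -1.67 (adjusted p = 5.09e-07; adjusted p = 0.411 with an estimated correlation) and 1.28 (adjusted p = 0.792), with HBA1 at -1.61 and 1.41, and SLC4A1 at -1.92 and 1.43. Of the red cell markers, 4 passed adjusted over the list alone in the 22 libraries, against 0 over all genes. HBA1 shares nearly all its sequence with HBA2, so its level is uncertain.

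Per-library indices, the mean log2 CPM of a marker list, were compared between the groups on the log scale. With 24 libraries the adipocyte index was 3.45 in prediabetes and 3.69 in controls (permutation p = 0.763), while the list's median log2 fold change was 2.01. The red cell index differed by -0.40 (permutation p = 0.577) while the list's median was 1.28, so for both lists the index and the fold changes had opposite signs. The slow minus fast fibre index was 1.5 ± 0.574 in controls and 1.7 ± 0.708 in prediabetes (SD, n = 14 and 10; two-sided permutation test, p = 0.455). Of 11 cell type indices, the macrophage index was 1.36 ± 0.391 in controls and 2.19 ± 1.32 in prediabetes (p = 0.0283, adjusted p = 0.311 over the 11, two-sided permutation test), and none had an adjusted p below 0.05. Without libraries 7 and 8 the macrophage index in prediabetes was 1.67 ± 0.798 (SD, n = 8; permutation p = 0.226). The adipocyte index was then 2.37 ± 1.05 against 3.69 ± 1.36 in controls (permutation p = 0.0306), and the T and NK cell, B cell and red cell indices differed from controls by -0.65, -0.51 and -1.19 (permutation p = 0.0418, 0.0389 and 0.0459, adjusted p = 0.126 for each of the 4, so none passed). Mitochondrially encoded genes took 21% ± 2.98 of counts in controls and 19.5% ± 4.30 in prediabetes (SD; permutation p = 0.327), and the 10 most abundant genes 25.4% ± 2.14 and 23.2% ± 4.94 (permutation p = 0.154). Haemoglobin genes took 0.0553% ± 0.0425 and 0.188% ± 0.460 (permutation p = 0.316), and 0.0168% ± 0.0116 in the 8 remaining prediabetes libraries (permutation p = 0.0205, adjusted p = 0.0615 over 3 shares).

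**Figure D3:**
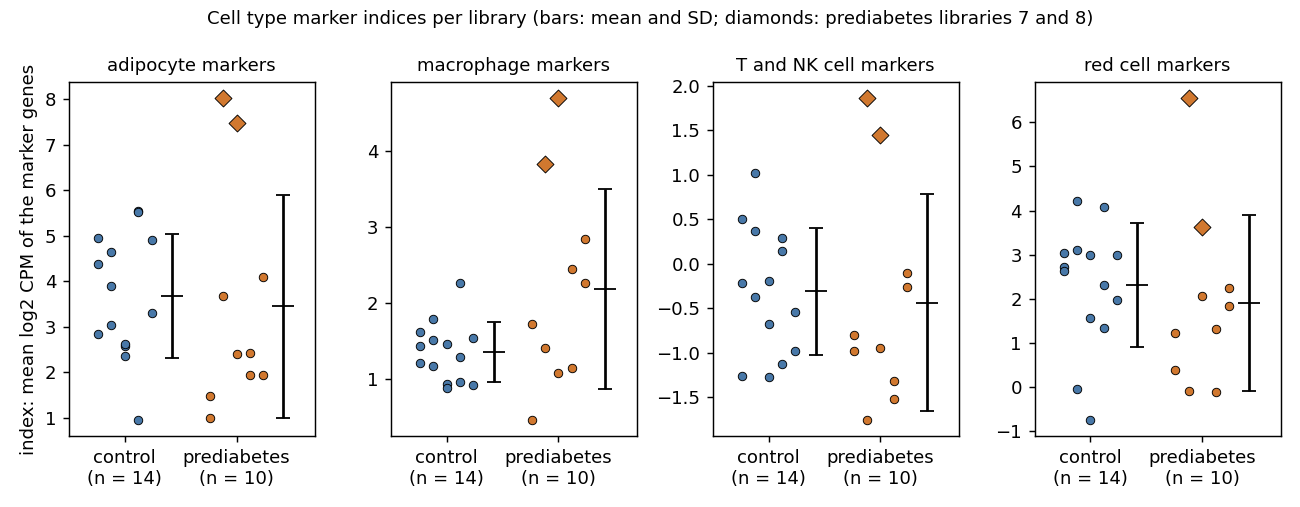
Indices of adipocyte, macrophage, T and NK cell, and red cell markers in each library (vertical axis, mean log2 CPM of the markers) by group. Points are libraries, diamonds are prediabetes libraries 7 and 8, and bars give the mean and SD of all 14 control and 10 prediabetes libraries. Libraries 7 and 8 had the highest values of the adipocyte, macrophage and T and NK cell indices.

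The remaining lists were called in neither set. With 24 libraries, those on the higher side were ceramide and sphingolipid metabolism (adjusted p = 0.0928), ER stress and unfolded protein response (adjusted p = 0.164), myostatin, activin and TGF beta signalling (adjusted p = 0.161), myokines and secreted muscle factors (adjusted p = 0.507), senescence and cell cycle arrest (adjusted p = 0.743), hypoxia and angiogenesis (adjusted p = 0.233) and smooth muscle and pericyte (adjusted p = 0.519). Those on the lower side were dystrophin complex and costamere (adjusted p = 0.0700), fatty acid uptake and oxidation (adjusted p = 0.117), insulin signalling and glucose uptake (adjusted p = 0.127), autophagy and lysosome (adjusted p = 0.324), oxidative stress defence (adjusted p = 0.406), metallothioneins (adjusted p = 0.959), glucocorticoid response (adjusted p = 0.0700), B and plasma cell (adjusted p = 0.959) and Schwann cell and nerve (adjusted p = 0.792). The median and the test differed in sign for the metallothionein, T and NK cell, B and plasma cell, red cell, and Schwann cell and nerve lists, whose medians were above 0 with the test on the lower side. For fatty acid uptake and oxidation, the mean (0.01) lay above 0 and the median (-0.08) below. The oxidative stress list likewise had a mean of 0.06 and a median of -0.01. In the 22 libraries the median and the test differed in sign for the dystrophin complex, mitochondrial biogenesis, autophagy, ER stress and myokine lists.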

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

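The tests of the 2 libraries that stand apart, of genes that vary together and of the macrophage contrasts were chosen after the results were seen, while the counts over other splits of the samples were planned before. In each measure of the 10 prediabetes libraries, the gap from the most extreme library to its nearest neighbour was divided by the range of the group and compared with Dixon's 95% critical value for 10 samples. Of 180 measures, 42 were above it, where chance gives about 1 in 20 for independent measures. These were not independent, as they include genes named by smallest p from lists whose members vary together. The count is therefore no test against chance. Prediabetes library 8 was the extreme one in 41 of them, the lowest in 40 and the highest in 1, and prediabetes library 7 in 1. As the gap is taken to the nearest neighbour, 2 libraries close together at the same end hide each other. The adipocyte index, at 8.03 and 7.48 in libraries 7 and 8 and at most 5.54 in the other 22, was therefore not flagged. This split between lowest and highest, and between both libraries, is in part set by the ratio itself.

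The percentage of counts in haemoglobin genes had a gap ratio of 0.820, with library 7 the highest, and RTL8B one of 0.572, with library 8 the highest. In the measures that follow, library 8 was the lowest after TMM scaling, in which its factor was 2.11. For HSPBAP1 this place depended on the scaling. Relative to the library total it was at 15.4 CPM in library 8 and 14.1 CPM in library 7. Myosin and other fibre genes had ratios as follows: MYH7 (0.789), MYH7B (0.687), MYL2 (0.820), CASQ2 (0.540), TPM3 (0.656), MYH2 (0.731), MYH1 (0.736), MYH4 (0.652), TNNT3 (0.733), MYL11 (0.791), MYL1 (0.816), TNNT2 (0.530) and MYH8 (0.582). Genes of the sarcomere, calcium handling and myogenesis were XIRP1 (0.795), LMOD2 (0.780), SLN (0.760), CACNA2D1 (0.656), MYF6 (0.768), EYA1 (0.597) and MEF2D (0.475). Among metabolic and mitochondrial genes were NDUFV3 (0.547), COX7A1 (0.558), PKM (0.501), PFKFB1 (0.483), STBD1 (0.506), PGM1 (0.557), GYG1 (0.471), ADSL (0.522), PPARGC1A (0.509), ESRRG (0.598), SLC2A4 (0.501) and IRS1 (0.502). The rest were FBXO32 (0.609), TRIM63 (0.718), UBE2D1 (0.595), HSPB8 (0.524), HSPBAP1 (0.476), DDIT4L (0.550), NR4A1 (0.491) and BHLHE41 (0.507).

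Prediabetes libraries 7 and 8 stood apart from the other 22 by low muscle and high adipocyte transcripts. Low sequencing depth is argued against by their totals, the lower of which was 56.2 M counts (mega-counts). A group-wide rise in prediabetes is argued against by the adipocyte index, which was 8.03 and 7.48 in libraries 7 and 8 and at most 5.54 in the other 22, and whose mean in the other 8 prediabetes libraries differed from controls by -1.31 (permutation p = 0.0306, adjusted p = 0.126 over 11 indices, so a fall is not shown). Tissue other than muscle in both samples may account for them, but library 7 is not shown to be a mixture of muscle and library 8's profile: its shares of both (0.449, quartiles 0.392 and 0.506, from 238 genes, and 0.384, quartiles 0.249 and 0.517, from 164 genes) summed to 0.832, within the bounds of 0.7 and 1.3 set for a mixture, but the lower quartiles sum to less than 0.7, and LEP (743 against 302 CPM), HBB (10914 against 1983 CPM) and COL1A1 (1527 against 1092 CPM) were higher in library 7 than in library 8. The genes for the shares were picked as at least 50-fold lower or 10-fold higher in library 8, where ACTA1 was at 48.5 CPM against 23588 to 41153 CPM in the other 22, so a biopsy rich in fat, a piece of another tissue and a wrong sample all stay open for it.

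With 24 libraries, 33 gene lists were called under a preset correlation. Chance could not be excluded, since 28 of 100 splits of the libraries gave as many (real 33, highest other 42), and the 43 splits that kept libraries 7 and 8 together called a median of 33 lists against 16.5 in the 56 that parted them, which points to a structure of the samples. Without covariates most of these calls depended on libraries 7 and 8. Without both, 4 were called again in the same direction, 27 were not called and 2 were called in the opposite one. Of the 33 lists, 16 changed direction. With the adipocyte index as a covariate, a different model, 17 were called in the same direction in the 22 libraries. How far the 2 libraries account for the calls under that model stays open, as all these calls used the preset correlation. An estimated correlation gave 0 in the 22 libraries (smallest adjusted p = 0.411) and was not fitted with the covariate. Genes that vary together may add to the calls, as the median correlation estimated within the called lists was 0.599 against the preset 0.01. Without the 2 libraries 74 of 100 splits gave as many lists (real 10, highest other 30), and tested 1 by 1 with an estimated correlation or fry no list was called in them (smallest adjusted p = 0.411 and 0.489), so a change with prediabetes in single lists is not shown.

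With all libraries the macrophage list was called higher with a preset correlation (adjusted p = 0.534 with an estimated correlation), and its index had an adjusted p of 0.311. Libraries 7 and 8 may account for much of it, as without them the macrophage index differed by 0.315 (permutation p = 0.226). A lower share of muscle that raises the markers of all other cell types alike is argued against in the 22 libraries. The macrophage index minus the mean of the other 10 indices was higher in prediabetes by 0.726 (permutation p = 6.20e-04, adjusted p = 0.00682 over 11 such contrasts, above the control median in 7 of 8). The mean of the other 10 differed by -0.41 (permutation p = 0.0659), so part of the contrast came from this lower mean. With the adipocyte and red cell indices left out of that mean the contrast was higher by 0.516 (permutation p = 0.00916). Against the endothelial, smooth muscle, fibroblast, Schwann cell and tendon indices 1 at a time, the macrophage index differed by 0.299, 0.374, 0.283, 0.628 and 0.105 (permutation p = 0.265, 0.277, 0.0706, 0.144 and 0.756). It was thus not shown to part from these 5, and a lower share of muscle that moves it together with them stays open. Against the adipocyte, T and NK, B, neutrophil and mast, and red cell indices it differed by 1.63, 0.966, 0.822, 0.648 and 1.51. The adjusted permutation p of these, over the 10 indices, ran from 0.0114 to 0.0353. Those 5 indices themselves differed from controls by -1.31, -0.651, -0.507, -0.333 and -1.19, so part of each difference came from these lower values. Because the contrast was chosen on these data, a change in macrophage transcripts with prediabetes is a hypothesis, and it remains untested on other samples.

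For genes with an unadjusted p under 0.05, chance could not be excluded: 10 of 100 splits gave as many with 24 libraries (real 2875, highest other 4402) and 50 of 100 without libraries 7 and 8 (real 852, highest other 2220). For genes called by edgeR the real count was 0 in both sets, which each of 100 splits must reach, so the splits decide nothing there (highest other 1 and 2).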

How the results depend on the processing

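The settings that leave out prediabetes libraries 7 and 8 together and those with an adipocyte covariate were chosen after seeing the data. The count of genes called, 0 with edgeR, was 2 with the DESeq2 Wald test, 580 with the adipocyte index as a covariate (481 higher and 99 lower) and from 0 to 2 when 1 library was left out at a time; the cause was not tested. With the same covariate in 22 libraries it was 0, with 1232 at an unadjusted p under 0.05. It was also 0 with DESeq2 size factors, no low count filter or an average CPM of at least 1, limma-voom with or without sample weights, the fibre, sex-linked, depth or surrogate variable covariates, and at an adjusted p threshold of 0.1. ABCC6, called by DESeq2, had log2 fold changes from 1.43 to 1.75 and adjusted p from 3.09e-04 to 0.987 over its alternatives. The count of lists called, 33, was 0 with an estimated correlation, 0 with fry, 18 with 3 surrogate variables, 10 in 22 libraries, 10 in 22 libraries with the sex-linked covariate, and 0 in 22 libraries with an estimated correlation or with fry; the cause was not tested. With surrogate variables 11 of the 33 calls kept their direction, and 3 (slow fibre, sarcomere and calcium handling) were called in the opposite one. The adipocyte covariate gave 34 lists, 32 of them shared in direction, and ended the immediate early call (adjusted p = 0.112). In 22 libraries the same covariate gave 22, of which 17 were shared in direction. An estimated correlation was not fitted with any covariate. DESeq2 size factors gave 33, the fibre covariate 30, without lipid storage (0.0606), inflammation (0.0892) and neutrophil and mast cell (0.0972), and the sex-linked covariate and the CPM filter 32 each, without tendon (0.101 and 0.0998). Leaving out 1 library at a time gave 28 to 35 lists, and 25 of the 33 calls were kept in all 24 such fits. Of the 193 genes that the naming rule gave, 44 were called with the adipocyte covariate in 24 libraries and 0 with it in 22. Of the same 193, the sign of the log2 fold change differed for 27 with surrogate variables, 7 with DESeq2, 4 with limma-voom, 33 with sample weights and 33 in 22 libraries. No paired analysis was possible because the replicate numbers follow accession order and pair no samples.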

Other observations

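The contrasts between cell type indices were chosen after the results were seen. Against the mean of the other 10 indices, in the 22 libraries without prediabetes 7 and 8, the fibroblast index differed by 0.415 (two-sided permutation p = 0.0157, adjusted p = 0.0863 over 11 contrasts) and the endothelial index by 0.397 (permutation p = 0.0659, adjusted p = 0.145). The adipocyte index differed by -1.07 (permutation p = 0.0379, adjusted p = 0.139) and the red cell index by -0.934 (permutation p = 0.0619, adjusted p = 0.145). The fibroblast and endothelial indices themselves differed by 0.0318 and 0.0153 (permutation p = 0.851 and 0.853), so both contrasts came from the lower mean of the other indices. Of these 11 contrasts only that of the macrophage index had an adjusted p below 0.05. The macrophage index itself differed by 0.315 (permutation p = 0.226), so part of its contrast came from that lower mean as well.

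Of the genes selected by the rule, the following 2 were singled out here after their values were seen. GDF11, a relative of myostatin, was below the control median in 10 of 10 prediabetes libraries after TMM scaling, with a log2 fold change of -0.84 ± 0.29 (SE) (edgeR adjusted p = 0.256) and -0.85 without libraries 7 and 8. The myogenic factor gene MYF6 was below it in 10 of 10 as well (-0.76 and -0.49).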
